A study of Mus musculus with 24 samples.

How the data were processed

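RNA was measured in the frontal pole of male DBA/2J mice, an inbred strain, after the olfactory bulbs had been taken off. The labels give 48 animals in 3 treatments of 16. SS mice received saline throughout. SE mice received saline until a first ethanol injection (2 g/kg) on test day 14. EE mice received ethanol on an earlier test day, then 10 daily ethanol injections (2.5 g/kg) and the same 2 g/kg challenge on day 14. Brains were taken 4 h after that last injection. Tissue of 4 animals was pooled, which gave 12 pools. Each pool was homogenised, cleared of nuclei and filtered, and then spun into a pellet called P2, enriched in synaptoneurosomes (resealed pre- and postsynaptic endings), and a cytosolic supernatant called S2. Total RNA of both fractions was sequenced, giving 24 libraries in 6 groups of 4. Replicates carry the numbers 3 to 6 in the labels, and P2 and S2 libraries with the same treatment and number were read as coming from the same pool, which the labels do not state. The deviations of such pairs from their group means correlated across genes, which are not independent replicates, at r between −0.20 and 0.29, with 1 of 12 pairs over 0.1. Set against the 4 libraries of its treatment in the other fraction, a choice of 1 among 4, each of 8 of 24 libraries correlated best with its own pool.

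The deposited table holds a value per assembled locus and library. Its header names no unit. The values were read as FPKM (sequenced fragments scaled to transcript length and to the mapped fragments of the library) because the submitters' processing notes name Cufflinks 2.1.1 and Cuffdiff 2.1.1, programs that give this unit, so the values are deposited as FPKM by inference. The submitters' processing notes also name CASAVA 1.8.2 and STAR, and the genome builds mm10 and GRCm38, without saying which step used which. Neither read counts nor any scaling between libraries is stated, so the depth of each library is unknown and no counting interval is given. The table has 28030 usable loci and 1 emptied line. Of the loci, 25680 carry a gene name and 2350 do not, 1159 name more than 1 gene, and 3148 repeat a symbol used at another locus. Gene positions were taken from the table, and gene descriptions and transcript GC content and length from the mouse reference annotation.

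Values were taken as log2(FPKM + 0.5). Named loci with a mean of at least 1 FPKM over the 24 libraries were tested, which left 12891. The tests used limma 3.58.1 in R 4.3.3, with the variance prior allowed to follow the mean level, and Benjamini-Hochberg adjustment over the loci of a comparison at 0.05. P2 was compared with S2 as the mean over the 3 treatments and within each treatment, from 1 model of the 6 group means over all 24 libraries. SE vs SS, EE vs SS and EE vs SE were each tested within P2 and within S2 on the 12 libraries of that fraction. For each pair of treatments the P2 effect minus the S2 effect was tested on all 24 libraries. Fold changes are log2 values with their standard error from the model. Group levels are means of 4 libraries with their SD.

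The gene lists (42 in all) were written before the data were examined, as were the comparisons, the tests, the thresholds, the rule for naming genes and most of the alternatives. A list entry was matched to the locus of that symbol that covers at least 50% of the gene's span and has the highest mean. That rule was chosen after the table had been seen, and it matched 1009 of 1028 entries in 41 lists. The 39 lists with at least 5 tested members were tested in every comparison by camera, which compares a list with all other loci, at its preset correlation between genes of 0.01. Camera was repeated with an estimated correlation. Adjusted p-values of lists are over the lists of 1 comparison. List counts are also given adjusted over the list alone.

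Genes were named by a rule. For P2 vs S2 these were the 8 highest and 8 lowest fold changes past the threshold with 1 direction in all 12 pools, and up to 4 members of each list with the smallest p. For a treatment comparison they were the 6 highest and 6 lowest past the threshold, or the 3 with the smallest p where fewer than 3 passed. Up to 4 members of each list called by camera were added. For a difference between fractions they were the 5 highest and 5 lowest, or the 3 with the smallest p. A panel of 10 genes, among them Fos, Arc, Bdnf, Fkbp5, Sgk1, Camk2a, Grin2b, Mbp and Ttr, was read in every treatment comparison. Some genes that the rule names are not reported here. Predicted genes and small RNAs were passed over. Among the genes so named, the text gives those measured at the locus that spans the gene. Extremes at further loci of a symbol, mostly fragments, are given as a count.

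The alternatives were pseudocounts of 0.1 and 1, no filter or a mean of at least 5, quantile normalisation, limma without the variance trend, a fixed block for the pool or for the replicate number, fits on the compared libraries alone, and leaving out each library in turn. Further alternatives were chosen after seeing the data. These were treating zeros listed in abundant loci as missing, removing from each library its trend on transcript GC content and length (a spline with 5 degrees of freedom, over the 11828 loci with both values), leaving EE P2 replicate 6 out of the list tests and of the SE vs SS test in P2, another locus rule, and quantile normalisation in the list tests. Every comparison was also run on other splits of the same libraries, all of them or 100 draws. On simulated data with 100 loci changed by each amount, EE vs SS in S2 recovered 76% of changes of 0.5 and 97% of changes of 1 on the log2 scale. SE vs SS in P2 recovered 30% and 79%, and the fraction difference of EE vs SS 22% and 76%. The simulated noise was independent between loci and had no GC trend, so recovery in the real data may be lower. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.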

Results

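The study followed RNA at and away from the synapse in mice that received ethanol for the first time or after repeated doses. Frontal pole tissue of saline-treated mice (SS), mice given a first ethanol injection (SE) and mice given ethanol after repeated ethanol (EE) was divided into a synaptoneurosome pellet (P2) and a cytosolic supernatant (S2), with 4 pooled libraries in each of the 6 groups. FPKM values per library summed to between 333645 and 575265, and the read depth is unknown. Libraries of the same group correlated with each other at r between 0.943 and 0.984 across genes, which are not independent replicates, apart from pairs with EE P2 replicate 6 (0.863 to 0.921). That library had the highest sum and held 17.8% of it in loci without a gene name.

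The first comparison asks which RNAs have a higher relative level in the synaptoneurosome pellet than in the cytosolic supernatant. FPKM are scaled to each library's own fragments, so they do not give the amount of RNA in a fraction. On this relative scale, RNA of astrocyte and microglia genes and of postsynaptic proteins was much higher in P2 than in S2. Most proteasome, chaperone and respiratory chain subunits were lower in P2, but those list calls were lost with an estimated correlation (adjusted p = 0.375, 0.32 and 0.712). Slc1a2, the main astrocyte glutamate transporter, averaged 1160 ± 123 FPKM in SS P2 against 132 ± 9.71 in SS S2 (SD, n = 4 each). Psmc2, an ATPase of the proteasome, averaged 18.7 ± 1.40 against 59.96 ± 1.70 FPKM (SD, n = 4 each). On mm10/GRCm38 coordinates Slc1a2 lies on chromosome 2 from 102657981 to 102984027 and Psmc2 on chromosome 5 from 21785010 to 21804074.

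The median P2 minus S2 value of all 12891 loci was −0.41 on the log2 scale and −0.08 after quantile normalisation, so gene and list values of this comparison are given as the distance above (positive) or below (negative) the median of all loci, whereas counts of higher and lower loci, and the limma p-values of genes, refer to the deposited difference from 0. Limma with Benjamini-Hochberg adjustment called 10828 loci, of which 2823 were higher in P2 and 8005 lower. After quantile normalisation the split was 4663 higher and 5712 lower of 10375. Every gene named here for P2 vs S2 had the stated direction in 12 of 12 pools.

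All 20 astrocyte markers were higher in P2, in the deposited and in the quantile-normalised values, with a list median of 1.77 (camera adjusted p = 1.68e-15, and adjusted p = 0.0193 with an estimated correlation). Slc1a2 lay 3.51 ± 0.08 above the median of all loci (limma adjusted p = 2.33e-18), the bicarbonate transporter gene Slc4a4 2.84 ± 0.06 and the glutamate transporter gene Slc1a3 2.43 ± 0.06. All 20 microglia markers were higher as well, also after quantile normalisation, with a median of 1.52 (adjusted p = 5.61e-14, and adjusted p = 0.0153 with an estimated correlation). Among them Itgam, a subunit of complement receptor 3, lay at 3.07 ± 0.05 (limma adjusted p = 7.42e-21), the protease gene Ctss at 2.01 ± 0.04 and the fractalkine receptor gene Cx3cr1 at 1.91 ± 0.04. Of 26 extracellular matrix and adhesion genes, 24 were higher and 1 lower (26 and 0 after quantile normalisation), with a median of 1.35 (adjusted p = 5.61e-14, and adjusted p = 0.0153 with an estimated correlation). Sparcl1, a secreted astrocyte protein that promotes synapse formation, lay at 2.27 ± 0.04 (limma adjusted p = 1.44e-19).

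Of 31 dendritic and postsynaptic mRNAs, 23 were higher in P2 and 5 lower (26 and 2 after quantile normalisation), with a median of 1.16 (camera adjusted p = 5.58e-09, and adjusted p = 0.0153 with an estimated correlation). Shank1, a scaffold of the postsynaptic density, lay at 3.07 ± 0.12 (limma adjusted p = 1.45e-14), the motor gene Kif5a at 2.54 ± 0.07 and the BDNF receptor gene Ntrk2 at 2.14 ± 0.04. Of 27 glutamate receptor subunits, 24 were higher and 1 lower (26 and 0 after quantile normalisation), with a median of 0.96 (adjusted p = 2.74e-11, and adjusted p = 0.0153 with an estimated correlation). The NMDA receptor subunit gene Grin2c lay at 2.33 ± 0.12 and the metabotropic receptor gene Grm3 at 2.04 ± 0.05. Of 36 potassium channel genes, 21 were higher and 7 lower (28 and 3 after quantile normalisation), with a median of 0.69 (adjusted p = 1.71e-05, and adjusted p = 0.05 with an estimated correlation, just inside the threshold). The glial channel gene Kcnj10 led them at 2.98 ± 0.04 (limma adjusted p = 1.18e-22). Which cells the transcripts of these lists came from was not tested, and astrocyte markers were higher in P2 as well.

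Of 31 proteasome subunits, 30 were lower in P2 and none higher (29 and 1 after quantile normalisation), with a median of −0.87 (camera adjusted p = 9.44e-06, and adjusted p = 0.375 with an estimated correlation). All 31 cytosolic chaperones were lower (27 after quantile normalisation), with a median of −0.66 (adjusted p = 1.09e-05, and adjusted p = 0.32 with an estimated correlation). Of 43 nuclear-encoded oxidative phosphorylation subunits, 38 were lower and none higher (33 and 5 after quantile normalisation), with a median of −0.61 (adjusted p = 0.0038, and adjusted p = 0.712 with an estimated correlation), a call that also ended with the pool as a block and the GC and length trend removed (adjusted p = 0.166). Psmc2 lay at −1.19 ± 0.05 (limma adjusted p = 1.19e-16), Cct3, a subunit of the chaperonin that folds actin and tubulin, at −0.95 ± 0.04, and the respiratory chain genes Ndufv2 and Uqcrc2 at −0.80 ± 0.06 and −0.61 ± 0.05.

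Other lists were mixed. Of 28 presynaptic vesicle and release genes, 6 were higher and 14 lower (11 and 13 after quantile normalisation; camera adjusted p = 0.866). The active zone gene Rims1 lay at 2.21 ± 0.06, whereas the synapsin gene Syn2 lay at −0.74 ± 0.04. Of 23 oligodendrocyte and myelin markers, 6 were higher and 11 lower as deposited and the majority turned to 11 higher and 6 lower after quantile normalisation (adjusted p = 0.299). Their median as deposited was −0.25, while camera, which compares with all other loci, gave an upward direction. Mbp, which encodes myelin basic protein, lay at 2.81 ± 0.13 and Mog, of the outer myelin surface, at −0.41 ± 0.07. The majority also turned for 50 cytosolic ribosomal proteins, from 1 higher and 28 lower to 21 higher and 6 lower (adjusted p = 0.952). Of 16 excitatory neuron markers 3 were higher and 11 lower, and of 18 interneuron markers 2 and 14, with 5 and 10, and 4 and 14, after quantile normalisation (adjusted p = 0.561 and 0.405). Neurod6, a transcription factor of cortical projection neurons, lay at −0.96 ± 0.06 and the calcium buffer gene Pvalb at −1.43 ± 0.08. Of 31 immediate early genes 2 were higher and 25 lower (6 and 20 after quantile normalisation; adjusted p = 0.146), with Egr1 at −0.74 ± 0.07. Adjusted over the list alone, the counts of all lists named for P2 vs S2 were the same, except for 26 in place of 28 ribosomal proteins lower. Fold changes between the fractions correlated with transcript length at a rank correlation of 0.39 across genes, which are not independent replicates.

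**Figure D1:**
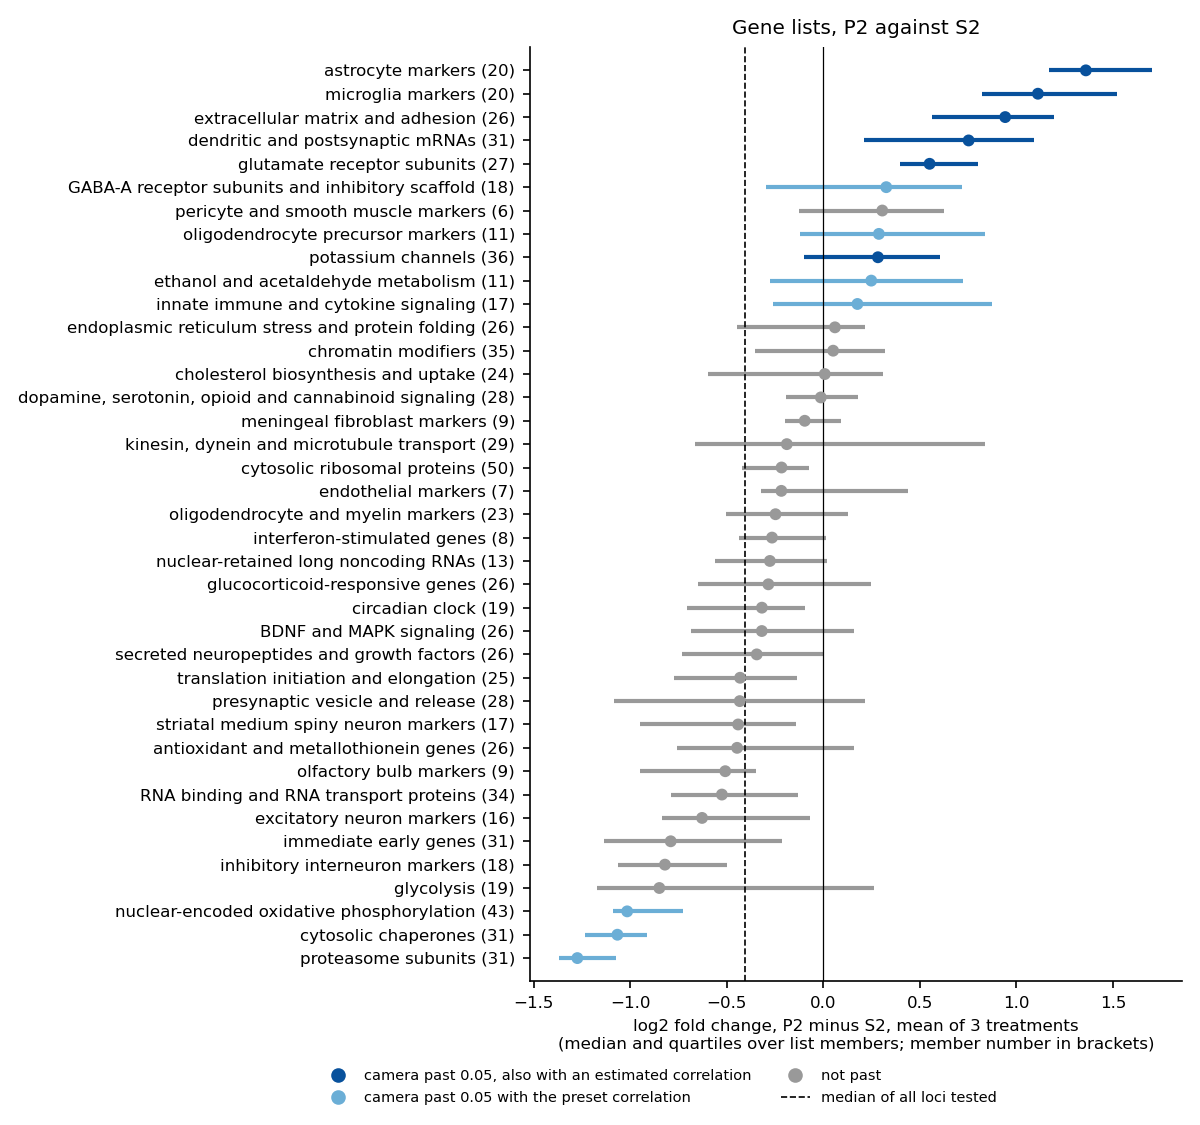
Median (point) and quartiles (line) of the log2 P2 minus S2 change of the members of 39 gene lists, with the median of all loci (−0.41) as a dashed line; dark blue lists pass 0.05 also with an estimated correlation, light blue lists with the preset correlation, grey lists with neither. Astrocyte, microglia, extracellular matrix, dendritic and glutamate receptor genes lie right of the dashed line and proteasome and chaperone genes left of it. Of the called myelin markers and ribosomal proteins, more were lower as deposited and more were higher after quantile normalisation.

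Within SS, SE and EE mice taken apart, limma called 9509 loci (2451 higher in P2, 7058 lower), 9262 (2275 and 6987) and 9292 (2305 and 6987). After quantile normalisation the splits were 4031 higher and 4750 lower of 8781, 3915 and 4675 of 8590, and 3843 and 4724 of 8567. Camera called the astrocyte, microglia, extracellular matrix, dendritic and glutamate receptor lists higher in P2 in each of the 3 treatments, with the estimated correlation as well.

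The comparison of SE with SS asks what a first dose of ethanol does. At 4 h after it, glucocorticoid-responsive genes were higher in both fractions. Fkbp5, a co-chaperone that restrains the glucocorticoid receptor, averaged 6.94 ± 0.468 FPKM in SS P2 and 20.5 ± 1.65 in SE P2, and 11.8 ± 0.289 in SS S2 and 22.7 ± 1.39 in SE S2 (SD, n = 4 each). Plin4, which coats lipid droplets, averaged 0.708 ± 0.113 and 3.89 ± 0.593 FPKM in P2, and 0.463 ± 0.0246 and 3.12 ± 0.481 in S2 (SD, n = 4 each). On mm10/GRCm38 coordinates Fkbp5 lies on chromosome 17 from 28398753 to 28486525 and Plin4 on chromosome 17 from 56100591 to 56109934.

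In P2, limma called 13 loci between SE and SS, all 13 higher. The count was 36 with the GC and length trend removed, 35 of them higher, and 8 with a mean of at least 5. Fkbp5 rose by 1.49 ± 0.09 (Benjamini-Hochberg adjusted p = 1.73e-05), Tsc22d3, which encodes the glucocorticoid-induced leucine zipper, by 1.14 ± 0.07 (adjusted p = 2.72e-05), the transcription factor gene Zbtb16 by 0.99 ± 0.09 (adjusted p = 0.00124) and Plin4 by 1.86 ± 0.19 (adjusted p = 0.00164). All 4 SE libraries lay above all 4 SS libraries for each. Of 26 glucocorticoid-responsive genes, 6 rose (11 adjusted over the list alone) and none fell, with a median of 0.28 (camera adjusted p = 5.82e-26, and adjusted p = 0.031 with an estimated correlation). Acss3, a mitochondrial acyl-CoA synthetase gene, rose by 1.38 ± 0.22 (adjusted p = 0.0466) in 4 of 4 libraries, a call lost without any 1 of the 8 SE and SS libraries (adjusted p from 0.0635 to 0.232), and with a pseudocount of 1 (0.0575), without a filter (0.0924), with a mean of at least 5 (0.055) or on the 8 libraries alone (0.0525). The count was 4 without SS P2 replicate 6 or SE P2 replicate 3 or 4, 5 without SS P2 replicate 5, and 7 without SS P2 replicate 4 or SE P2 replicate 5.

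Camera also called 28 presynaptic genes (median −0.17, adjusted p = 9.74e-08) and 27 glutamate receptor subunits (median −0.11, adjusted p = 0.000917) lower in SE P2, but none of their members passed, also adjusted over the list alone, and the adjusted p was 0.509 with an estimated correlation for both. The synaptic vesicle gene Syp was at −0.31 ± 0.15 and the kainate receptor gene Grik3 at −0.24 ± 0.10. The 31 immediate early genes had a median of 0.11 (adjusted p = 0.0017, and adjusted p = 0.781 with an estimated correlation). The 19 glycolysis genes were called lower (adjusted p = 0.023, and adjusted p = 0.781 with an estimated correlation), although their median was −0.12 and their mean 0.02, and the call was lost after quantile normalisation (adjusted p = 0.43).

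In S2, limma called 69 loci between SE and SS, 49 higher and 20 lower. With the GC and length trend removed it called 127, 80 higher and 47 lower. Plin4 rose by 1.90 ± 0.10 (adjusted p = 3.12e-06), Fkbp5 by 0.91 ± 0.06 (adjusted p = 1.73e-05), Mfsd2a, a lipid transporter of the blood-brain barrier, by 0.97 ± 0.07 (adjusted p = 7.42e-05), Zbtb16 by 0.69 ± 0.07 (adjusted p = 0.00174) and Hif3a by 0.80 ± 0.09 (adjusted p = 0.00293), each in 4 of 4 libraries. The myelin gene Opalin fell by 0.44 ± 0.06 (adjusted p = 0.00958) in 4 of 4 libraries. Of 26 glucocorticoid-responsive genes, 10 rose (15 adjusted over the list alone) and none fell, with a median of 0.31 (camera adjusted p = 1.5e-23, and adjusted p = 0.0121 with an estimated correlation). Of the 13 and 49 loci higher in P2 and in S2, 10 were shared, Fkbp5, Plin4, Tsc22d3 and Zbtb16 among them. Both lists come from the same 8 pools as read from the replicate numbers. The S2 count was 26 without SE S2 replicate 5, 32 without SS S2 replicate 3, 4 or 5 or SE S2 replicate 3, 34 without SS S2 replicate 6 and 37 without SE S2 replicate 4.

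The 31 immediate early genes, a readout of recent neuronal activity, had a median of 0.18 in S2 (camera adjusted p = 1.28e-05, and adjusted p = 0.664 with an estimated correlation). None passed over all loci and 3 did adjusted over the list alone. Fos was at 0.69 ± 0.22 (limma adjusted p = 0.278), Egr1 at 0.54 ± 0.13 (adjusted p = 0.123) and Jun at 0.36 ± 0.08 (adjusted p = 0.0778). Camera called smaller shifts of the striatal neuron markers (median 0.11) and of the cholesterol genes (median −0.06, adjusted p = 0.00471 for both, and adjusted p = 0.696 for both with an estimated correlation). The same held for the oxidative phosphorylation genes (median −0.08, adjusted p = 0.0012) and the ribosomal proteins (median −0.09, adjusted p = 0.00187), with an adjusted p = 0.812 for both with an estimated correlation. Camera called 3 further lists with medians of 0.09 (dopamine, serotonin, opioid and cannabinoid genes), −0.13 (interferon-stimulated genes) and −0.06 (proteasome subunits). The last 2 calls ended with the GC and length trend removed (adjusted p = 0.14 and 0.374), and with an estimated correlation their adjusted p was 0.617, 0.511 and 0.812. Of the striatal, cholesterol, oxidative phosphorylation and ribosomal lists no member passed over all loci, and adjusted over the list alone 2 cholesterol genes were lower. Sgk1, a kinase gene induced by glucocorticoids, was at 0.33 ± 0.09 (adjusted p = 0.15) in S2, and Camk2a and Mbp were at −0.01 ± 0.06 and 0.08 ± 0.09.

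**Figure D2:**
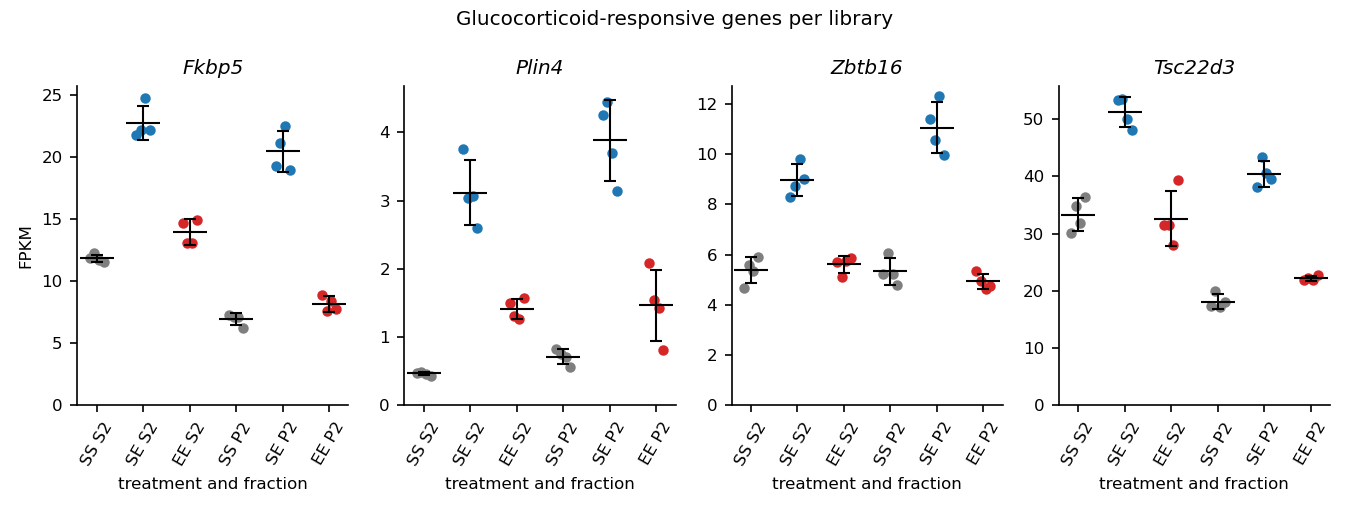
FPKM of Fkbp5, Plin4, Zbtb16 and Tsc22d3 in every library (points), with the mean and SD of 4 libraries, in the 6 groups of treatment and fraction. All 4 SE libraries of a fraction lie above its SS and EE libraries, for Fkbp5 at a mean of 20.5 FPKM in SE P2 against 6.94 in SS P2 and 8.15 in EE P2.

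The comparison of EE with SE asks how mice with repeated ethanol before the challenge differed from mice given only the challenge. No group received repeated ethanol without the challenge. An altered response to it therefore cannot be told apart from a lasting effect of the repeated doses. Of 26 glucocorticoid-responsive genes, 3 were lower in EE than in SE in P2 and 13 in S2, and of 26 genes of endoplasmic reticulum (ER) stress and folding 8 were higher in EE S2. The list calls were lost with an estimated correlation (adjusted p = 0.157, 0.393 and 0.871). Fkbp5 averaged 8.15 ± 0.622 FPKM in EE P2 and 13.9 ± 1.04 in EE S2, and Plin4 1.46 ± 0.519 and 1.41 ± 0.149 (SD, n = 4 each). The SE means were 20.5 and 22.7 FPKM for Fkbp5 and 3.89 and 3.12 for Plin4.

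In P2, limma called 7 loci between EE and SE, all 7 lower in EE. Fkbp5 fell by 1.28 ± 0.09 (Benjamini-Hochberg adjusted p = 0.0001), Zbtb16 by 1.09 ± 0.09 (adjusted p = 0.000446) and Tsc22d3 by 0.85 ± 0.07 (adjusted p = 0.000446), each in 4 of 4 libraries. Of 26 glucocorticoid-responsive genes, 3 fell (17 adjusted over the list alone) and none rose, with a median of −0.47 (camera adjusted p = 1.37e-15, and adjusted p = 0.157 with an estimated correlation). The 31 immediate early genes had a median of −0.30 (adjusted p = 0.000601, and adjusted p = 0.942 with an estimated correlation), with Fosb at −0.54 ± 0.12 (limma adjusted p = 0.314). The 26 genes of ER stress and folding had a median of 0.12 (adjusted p = 0.000338) and the 31 cytosolic chaperones one of 0.17 (adjusted p = 1.78e-05), with an adjusted p = 0.942 for both with an estimated correlation. No member of these lists passed over all loci, and adjusted over the list alone 4 ER genes and 1 chaperone were higher and 2 immediate early genes lower. Hspa5, the main chaperone of the ER, averaged 215 ± 12.2 FPKM in EE P2 and 161 ± 15.8 in SE P2 (SD, n = 4 each), a change of 0.42 ± 0.09 that did not pass (adjusted p = 0.275). Camera also called the 18 GABA-A receptor and scaffold genes (median 0.27, adjusted p = 0.0115) and the 34 RNA binding and transport genes (median 0.20, adjusted p = 0.000338) higher, with an adjusted p = 0.942 for both with an estimated correlation. The GABA-A call was lost without EE P2 replicate 6 (adjusted p = 0.102). With the GC and length trend removed the RNA binding median was −0.03 (adjusted p = 0.928) and the call of the immediate early genes ended (adjusted p = 0.0833). The P2 count was 4 on the 8 libraries alone or without SE P2 replicate 4 or EE P2 replicate 5.

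In S2, limma called 1077 loci between EE and SE, 478 higher and 599 lower (730 and 470 of 1200 after quantile normalisation). The count was 142 on the 8 libraries alone and 601 without a filter. All 12 loci with the highest and lowest fold changes lay at further loci of a symbol. Fkbp5 fell by 0.69 ± 0.06 (adjusted p = 0.000803), Hif3a by 0.94 ± 0.09 (adjusted p = 0.00147), Plin4 by 0.91 ± 0.10 (adjusted p = 0.00169) and Zbtb16 by 0.63 ± 0.07 (adjusted p = 0.00229), each in 4 of 4 libraries. Of 26 glucocorticoid-responsive genes, 13 fell (15 adjusted over the list alone) and none rose, with a median of −0.28 (camera adjusted p = 1.03e-07, and adjusted p = 0.393 with an estimated correlation). Of 26 genes of ER stress and folding, 8 rose and none fell (11 and 1 adjusted over the list alone; camera adjusted p = 0.00214, and adjusted p = 0.871 with an estimated correlation). Hyou1, an ER chaperone, rose by 0.40 ± 0.04 (limma adjusted p = 0.00169) and Pdia6, a disulfide isomerase, by 0.40 ± 0.06 (adjusted p = 0.00774). Of 31 cytosolic chaperones, 5 rose and none fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000162, and adjusted p = 0.871 with an estimated correlation). The inducible heat shock gene Hspa1b rose by 0.77 ± 0.13 (limma adjusted p = 0.00892) and Stip1, which links heat shock proteins 70 and 90, by 0.43 ± 0.07 (adjusted p = 0.00751). Of 31 dendritic and postsynaptic mRNAs, 9 rose and none fell (15 and 4 adjusted over the list alone; camera adjusted p = 0.00163, and adjusted p = 0.871 with an estimated correlation), with Begain at 0.43 ± 0.07 (limma adjusted p = 0.00855). The genes named here lay in 4 of 4 EE libraries on the stated side of all SE libraries. Camera called 5 further lists, each with an adjusted p = 0.871 with an estimated correlation, with medians of 0.09 (presynaptic), 0.12 (striatal), 0.10 (glycolysis), 0.07 (chromatin modifiers) and −0.10 (RNA binding). All 5 of these calls ended with the GC and length trend removed (adjusted p from 0.0556 to 0.772), and the first 3 also after quantile normalisation (adjusted p = 0.185 for each).

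These S2 counts moved with single libraries. The count was 152 without SE S2 replicate 3, 184 without SE S2 replicate 4, 154 without SE S2 replicate 5, 2010 without SE S2 replicate 6, 223 without EE S2 replicate 3, 1985 without EE S2 replicate 5 and 626 without EE S2 replicate 6. Fold changes between EE and SE correlated with transcript GC content across genes, which are not independent replicates, at a rank correlation of 0.54 in S2 and −0.73 in P2. After the GC and length trend of each library was removed, 623 loci were called in S2 (216 higher, 407 lower) and 20 in P2 (5 higher, 15 lower).

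The comparison of EE with SS gives the whole difference between repeated ethanol with the challenge and saline. In S2 of EE mice, 8 of 26 genes of protein folding in the ER, 8 of 31 immediate early genes, 11 of 31 postsynaptic genes and 5 of 17 striatal neuron markers were higher, and 7 of 24 cholesterol genes were lower. None of these list calls held with an estimated correlation (adjusted p = 0.691 for the first 4 and 0.737 for the last). Hyou1 averaged 40.8 ± 2.12 FPKM in EE S2 and 30.0 ± 1.23 in SS S2, and Pdia6 63.4 ± 3.69 and 47.6 ± 2.99 (SD, n = 4 each). Hyou1 lies on chromosome 9 from 44379490 to 44392369 and Pdia6 on chromosome 12 from 17246656 to 17284770 on mm10/GRCm38 coordinates.

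Of 26 genes of ER stress and folding, 8 rose in EE S2 and none fell (10 and 0 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 8.78e-05, and adjusted p = 0.691 with an estimated correlation). Hyou1 rose by 0.44 ± 0.04 (limma adjusted p = 0.0013), Pdia6 by 0.41 ± 0.06 (adjusted p = 0.00569), Sdf2l1 by 0.61 ± 0.11 (adjusted p = 0.00984) and Hspa5 by 0.38 ± 0.07 (adjusted p = 0.0127). Of 31 immediate early genes, 8 rose and none fell (10 and 0 adjusted over the list alone), with a median of 0.28 (camera adjusted p = 5.58e-05, and adjusted p = 0.691 with an estimated correlation). Jun rose by 0.56 ± 0.08 (limma adjusted p = 0.00427) and Fosl2 by 0.34 ± 0.07 (adjusted p = 0.0148), while Fos (0.43) and Arc (0.37) did not pass. Of 31 dendritic and postsynaptic mRNAs, 11 rose and 1 fell (16 and 3 adjusted over the list alone), with a median of 0.18 (camera adjusted p = 5.58e-05, and adjusted p = 0.691 with an estimated correlation). Gria1, an AMPA receptor subunit, rose by 0.29 ± 0.06 (limma adjusted p = 0.0137). Of 17 markers of striatal medium spiny neurons, 5 rose and none fell (10 and 0 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.000115, and adjusted p = 0.691 with an estimated correlation). The orphan receptor gene Gpr6 rose by 0.48 ± 0.08 (limma adjusted p = 0.00659) and the dopamine D2 receptor gene Drd2 by 0.46 ± 0.10 (adjusted p = 0.0167). Each gene named as changed lay in 4 of 4 EE libraries beyond all SS libraries.

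Of 24 genes of cholesterol synthesis and uptake, 7 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of −0.13 (camera adjusted p = 0.03, and adjusted p = 0.737 with an estimated correlation). Idi1, an isomerase of the mevalonate pathway, fell by 0.45 ± 0.06 (limma adjusted p = 0.00413) and the synthase gene Hmgcs1 of the same pathway by 0.33 ± 0.05 (adjusted p = 0.00419), each in 4 of 4 libraries. Of 43 oxidative phosphorylation genes, 5 fell and none rose (also adjusted over the list alone), with a median of −0.15 (camera adjusted p = 0.00215, and adjusted p = 0.737 with an estimated correlation). Ndufa10 fell by 0.30 ± 0.06 (limma adjusted p = 0.00961) and Uqcrfs1 by 0.32 ± 0.06 (adjusted p = 0.00976), in 4 of 4 libraries. Of 31 cytosolic chaperones, 5 rose and none fell (also adjusted over the list alone), with a median of 0.03 (camera adjusted p = 0.0157, adjusted p = 0.737 with an estimated correlation, and 0.133 after quantile normalisation). Hspa1b rose by 0.71 ± 0.13 (limma adjusted p = 0.0095) in 4 of 4 libraries. Camera called 50 ribosomal proteins (median −0.13, adjusted p = 0.00495) and 34 RNA binding and transport genes (median −0.13, adjusted p = 0.025) lower, calls that ended once the GC and length trend was removed (adjusted p = 0.0779 and 0.95). For both, the adjusted p was 0.737 with an estimated correlation. Of the ribosomal proteins 2 fell, and of the RNA binding genes 4 fell and 1 rose (2, and 8 and 2, adjusted over the list alone).

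In S2, limma called 1662 loci in all, 718 higher in EE and 944 lower (1102 and 748 of 1850 after quantile normalisation). Of the 12 with the highest and lowest fold changes, 11 lay at further loci of a symbol. Glial markers had medians of 0.05 (astrocyte), −0.06 (microglia) and −0.02 (myelin) in this comparison, with camera adjusted p = 0.49, 0.59 and 0.83. Of these lists the astrocyte and microglia markers were called higher in P2 than in S2, and the myelin markers were not. Fold changes followed transcript GC content at a rank correlation of 0.48 across genes, which are not independent replicates, and with the GC and length trend removed 1048 loci were called (352 higher, 696 lower). The count was 1006 on the 8 libraries alone, 1023 without a filter, 852 without SS S2 replicate 3, 1010 without SS S2 replicate 4, 586 without SS S2 replicate 5, 636 without SS S2 replicate 6 and 491 without EE S2 replicate 3.

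**Figure D3:**
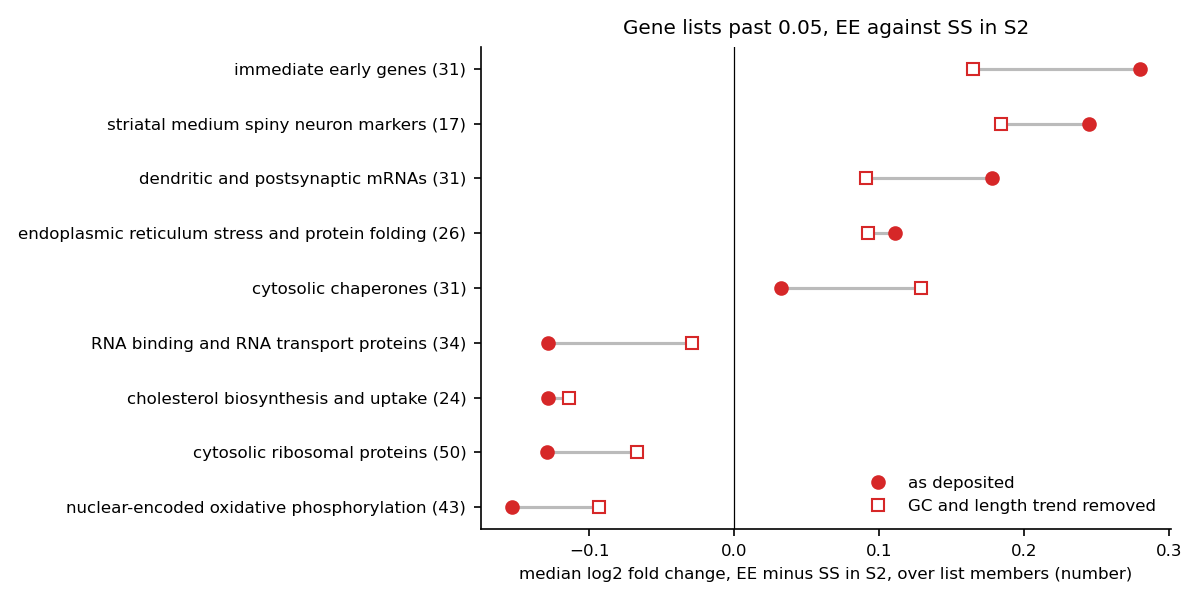
Median log2 change between EE and SS in S2 of the 9 gene lists past 0.05 with the preset correlation, as deposited and with the GC and length trend of each library removed. All 9 medians keep their sign, from 0.28 to 0.16 for immediate early genes and from 0.11 to 0.09 for genes of ER stress and folding; none of the 9 calls holds with an estimated correlation.

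**Figure D4:**
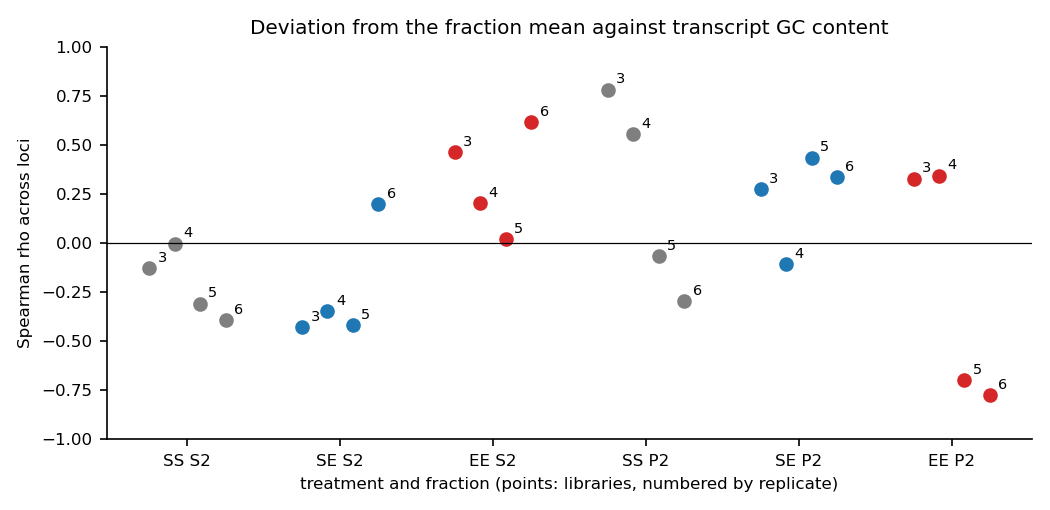
Rank correlation across genes between a library's deviation from its fraction's mean and transcript GC content, for each of the 24 libraries (numbers are replicates). EE S2 libraries lie between 0.02 and 0.62 and SS S2 libraries between −0.39 and 0.00, whereas in P2 EE replicates 5 and 6 lie at −0.70 and −0.77 and EE replicates 3 and 4 at 0.33 and 0.34.

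In P2, limma called 1 locus between EE and SS, against 2332 at an unadjusted p under 0.05. Acss3 averaged 6.16 ± 1.88 FPKM in EE P2 and 1.41 ± 0.456 in SS P2 (SD, n = 4 each). It rose by 1.79 ± 0.22 (Benjamini-Hochberg adjusted p = 0.047) in 4 of 4 libraries. Agxt2l1 was at 0.76 ± 0.11 (adjusted p = 0.0684) and the cadherin gene Cdh4 at −0.52 ± 0.08 (adjusted p = 0.0941), and neither passed. Fkbp5 was at 0.22 ± 0.09 (adjusted p = 0.273) in P2. In S2 it rose by 0.22 ± 0.06 (adjusted p = 0.0311), a call lost without SS S2 replicate 3 (0.0625), 5 (0.0762) or 6 (0.0792) or EE S2 replicate 3 (0.0905) or 6 (0.0629), on the 8 libraries alone (0.0527), and with the GC and length trend removed (0.16, adjusted p = 0.071). Of 26 glucocorticoid-responsive genes none passed in P2 (3 rose adjusted over the list alone; median −0.08, camera adjusted p = 0.89), and in S2 4 rose and 2 fell (also adjusted over the list alone; median −0.01, adjusted p = 0.23). Acss3 lost its call without SS P2 replicate 3 (adjusted p = 0.152), 4 (0.0791), 5 (0.0502) or 6 (0.0904) or EE P2 replicate 4 (0.15) or 5 (0.144), and the count was then 0, against 2 without EE P2 replicate 3 or with a pseudocount of 0.1, and 3 without EE P2 replicate 6 or with the GC and length trend removed. The Acss3 call was also lost with a pseudocount of 1 (0.0503), without a filter (0.128) and on the 8 libraries alone (0.282).

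Camera called 28 presynaptic genes lower in EE P2 than in SS P2 (median −0.29, adjusted p = 0.000658), with 1 lower adjusted over the list alone, and 19 glycolysis genes (median −0.28, adjusted p = 0.00262), also with 1. Both calls were lost with an estimated correlation (adjusted p = 0.989). Unc13a, which primes synaptic vesicles, was at −0.52 ± 0.13 (limma adjusted p = 0.273). The 34 RNA binding and transport genes were called higher (median 0.27, adjusted p = 0.000658), but their median was −0.07 once the GC and length trend was removed (adjusted p = 0.958), and the adjusted p was 0.989 with an estimated correlation. The 31 cytosolic chaperones had a median of 0.13 (adjusted p = 0.0318, and adjusted p = 0.989 with an estimated correlation), with none past adjusted over the list alone. Fold changes followed GC content at a rank correlation of −0.77 across genes in this comparison.

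The last set of comparisons asks whether treatments acted differently in the synaptoneurosome pellet and in the supernatant. For SE vs SS, limma called 0 loci (236 at an unadjusted p under 0.05). It called 2 with a mean of at least 5 and 1 with the pool as a block and the GC and length trend removed. The P2 minus S2 difference was 0.58 ± 0.10 for Fkbp5 (adjusted p = 0.0758) and 0.52 ± 0.12 for Tsc22d3 (adjusted p = 0.879). Camera called the 28 presynaptic genes (median −0.14, adjusted p = 1.52e-05), the 27 glutamate receptor subunits (−0.12, adjusted p = 0.000403) and the 28 dopamine, serotonin, opioid and cannabinoid genes (−0.17, adjusted p = 0.000403) lower in P2 relative to S2. With an estimated correlation the adjusted p was 0.574, 0.574 and 0.307. The glucocorticoid-responsive genes had a median of 0.04 (adjusted p = 0.0227, and adjusted p = 0.574 with an estimated correlation). The other 8 lists called had medians between −0.11 and 0.20, and an adjusted p up to 0.947 with an estimated correlation. Of these, the ribosomal, extracellular matrix and glycolysis calls were lost with the pool as a block (adjusted p = 0.104, 0.0583 and 0.0511).

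For EE vs SS, limma called 344 loci whose change differed between P2 and S2, 180 higher and 164 lower (307 and 553 of 860 after quantile normalisation), and 7 when the pool, as read from the replicate numbers, was fitted as a block (11 with the GC and length trend also removed). Without a filter the count was 65. The differences followed GC content at a rank correlation of −0.77 across genes, which are not independent replicates. Of 28 presynaptic genes 2 were lower in P2 relative to S2 (13 adjusted over the list alone), with a median of −0.41 (camera adjusted p = 0.000603). That call was lost with an estimated correlation (adjusted p = 0.952), and with the pool as a block and the GC and length trend removed (adjusted p = 0.0841). The 31 immediate early genes had a median of −0.44 (adjusted p = 0.00967) with none past over all loci, and 34 RNA binding and transport genes one of 0.30 (adjusted p = 0.000603, 10 higher adjusted over the list alone) that was −0.03 with the block and trend removal. Both calls were lost with an estimated correlation (adjusted p = 0.952) and with the block and trend removal (adjusted p = 0.247 and 0.975). The 19 glycolysis genes had a median of −0.38 (adjusted p = 0.00221), with 1 lower (2 adjusted over the list alone), and the adjusted p was 0.952 with an estimated correlation. The count was 19 without SS S2 replicate 3 or EE S2 replicate 3, 26 without SS S2 replicate 4, 24 without SS S2 replicate 5, 9 without SS S2 replicate 6, 47 without EE S2 replicate 5 and 16 without EE S2 replicate 6. It was 29 without SS P2 replicate 3, 7 without SS P2 replicate 4, 1482 without SS P2 replicate 5, 2245 without SS P2 replicate 6, 3292 without EE P2 replicate 3, 3346 without EE P2 replicate 4, 33 without EE P2 replicate 5 and 59 without EE P2 replicate 6.

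For EE vs SE, limma called 9 loci, 4 higher and 5 lower in P2 relative to S2, and 1 with the pool as a block. The count was 3 with the GC and length trend also removed and 5 with a mean of at least 5. Across genes, which are not independent replicates, the differences followed GC content at a rank correlation of −0.78. The P2 minus S2 difference was −0.59 ± 0.10 for Fkbp5 (adjusted p = 0.0314, and 0.0699 with the block) and −1.26 ± 0.20 for Nova2, a neuronal splicing factor (adjusted p = 0.0169, 0.0526 with the block, and 0.102 at −1.03 with the trend also removed). Camera called the RNA binding (median 0.27, but −0.07 with the GC and length trend removed), glycolysis (−0.35), immediate early (−0.32) and chromatin modifier (−0.16) lists, with an adjusted p = 0.864 for each with an estimated correlation. These calls ended with the pool as a block and the trend removed (adjusted p from 0.092 to 0.955), and that of the chromatin modifiers with the block alone (0.072). Fkbp5 lost its call without SE S2 replicate 3 (0.0668) or 4 (0.0921), EE S2 replicate 3 (0.0957) or 6 (0.0706), SE P2 replicate 4 (0.0627) or 5 (0.0966) or EE P2 replicate 5 (0.063), and Nova2 without EE S2 replicate 3 (0.0662), SE P2 replicate 5 (0.0663) or EE P2 replicate 5 (0.063). The count was 2 without SE S2 replicate 3 or 4 or SE P2 replicate 4, 3 without SE S2 replicate 5, EE S2 replicate 5 or 6 or SE P2 replicate 3, 1 without EE S2 replicate 3, SE P2 replicate 5 or EE P2 replicate 5, 15 without EE S2 replicate 4, 19 without EE P2 replicate 3, 14 without EE P2 replicate 4 and 6 without EE P2 replicate 6.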

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

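The removal of the GC and length trend, the 2 tests for P2 material in the EE supernatants, the test for a supernatant library under a P2 name and the test of astrocyte and endothelial RNA were chosen after the results had been seen. The 2 tests for P2 material replaced a sign test of the glial marker lists, which had left it open (microglia median −0.06, exact two-sided p = 0.115 over 20 genes; astrocyte 0.05, p = 0.263; myelin −0.02, p = 1), and the marker levels were tested after the directions.

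Repeated ethanol went with 1662 called loci in S2 against SS and 1077 against SE, and the change from SS differed between fractions at 344 loci. A trend on transcript GC content and length was argued against as the whole cause in S2. With it removed, 1048 loci were called against SS (63.1% of the count; 669 of 1550 with GC and length values past in both) and 623 against SE (57.8%; 408 of 988). For the fraction difference the trend was removed only in the fit with the pool as a block, which called 7 loci before and 11 after. The block alone had taken the count from 344 to 7, so this fit cannot tell whether a GC trend lies behind the 344. The differences of all loci followed GC content at a rank correlation of −0.77 across genes, which are not independent replicates. P2 material in the EE supernatants at a 27.6% share of SS P2 was argued against by marker levels. That share is the lower quartile of what the 1106 called loci that moved toward P2 need, and the other called loci did not enter it. At that share 39 of 41 glial markers higher in P2 (95.1%) were below the level due in all 4 EE libraries. The median share read from these markers was 0.12%, and smaller shares than 27.6% were not tested. Direction could not decide it. Of 1310 called loci with a P2 minus S2 difference past the threshold in SS, 1106 moved toward P2, and 12.3% of all called loci moved against that difference. Both differences subtract the same 4 SS S2 libraries, so noise in these pushes the 2 directions to agree. An effect of repeated ethanol itself stays open, and other differences between the EE and SS tissue were not tested.

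The EE P2 replicate 6 library stood apart from the other P2 libraries, with the highest FPKM sum (575265), 17.8% of it in loci without a gene name and 33.5% in its top 10 named loci. A GC and length trend was argued against as the whole cause, because the SD of its log2 deviations from the P2 mean was 0.713 with the trend removed (0.901 before), against 0.44 in the next library, SS P2 replicate 3. A supernatant library under a P2 name was argued against, since its correlation across genes was 0.878 with the mean of the other P2 libraries and 0.824 with the S2 mean, a difference of 0.0539. A few loci taking a large part of the sum and RNA from another source stay open. No biological explanation was tested.

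Glucocorticoid-responsive genes were higher in SE than in SS, and 3 of 26 in P2 and 13 in S2 were lower in EE than in SE, where the list call was lost with an estimated correlation (adjusted p = 0.157 in P2 and 0.393 in S2). Noise in the shared SE libraries was argued against, because with 2 SE libraries set against SS and the other 2 against EE the highest of the 12 list medians of EE minus SE was −0.23. A GC and length trend was argued against for SE minus SS, since its list median kept 96.8% of its value in S2 and 112% in P2 with the trend removed. More astrocyte or endothelial RNA in SE was argued against for SE minus SS, since the highest of their 4 marker medians was 14.0% of the glucocorticoid list's median. Neither explanation was weighed here for the lower values in EE than in SE. Fold changes of EE vs SE followed GC content more strongly than those of SE vs SS (rank correlation −0.73 in P2 and 0.54 in S2). A smaller response of these genes to ethanol after repeated doses may account for the pattern, as a hypothesis found on these data and not itself tested. It cannot be told apart from a lasting effect of the repeated doses, since no group received them without the challenge. No hormone level is among the values used here.

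For the following counts, a share under 0.05 of the splits of the same libraries, the real one included, called as many loci. These shares were not adjusted over the comparisons. Splits also cannot separate a treatment from a library difference that goes with it, such as the GC trend in S2. For P2 vs S2, 1 of 100 splits, the real one, called as many loci (10828, highest other 10109). These splits exchanged P2 and S2 in randomly drawn pools, so one that exchanges few pools keeps most of the real contrast. The cause of the high count was not tested. Of 35 splits only the real 1 called as many for SE vs SS in P2 (13, highest other 1) and S2 (69, 0), EE vs SE in P2 (7, 1) and S2 (1077, 539), EE vs SS in S2 (1662, 0) and the fraction difference of EE vs SS (344, 2). With the trend removed the highest other split was 0 for EE vs SS and 171 for EE vs SE in S2 (real 1048 and 623), and with the pool as a block it was 1 for the fraction difference of EE vs SS (real 7). Chance could not be excluded for EE vs SS in P2 (3 of 35 splits; real 1, highest other 4) or for the fraction difference of EE vs SE (2 of 35; real 9, highest other 193). The last split called several times the real count, which points to a structure of the samples. For the fraction difference of SE vs SS limma called 0 loci (236 at an unadjusted p under 0.05), so each of the 35 splits has as many by construction (35 of 35, highest other 0) and their number says nothing about chance. Within SS, SE and EE mice, P2 vs S2 has 8 splits that part all pairs, too few for a share under 0.05 (1 of 8 each; real 9509, 9262 and 9292, highest other 2, 4 and 1967). The 27 other splits of each, which part fewer pairs, called at most 1 locus in SS and 0 in SE but up to 4272 in EE, which points to a structure of the EE libraries.

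The fraction difference of EE vs SE was called at 9 loci, with Fkbp5 at −0.59, Nova2 at −1.26, Ext1 at 0.62 and Ube2r2 at 0.49 (P2 effect minus S2 effect, log2). Ext1 (adjusted p = 0.0359) lost its call with the pool as a block (0.0699), with the block and the GC and length trend removed (0.28, adjusted p = 0.555), and without SE S2 replicate 3 (0.0646), 4 (0.0921), 5 (0.105) or 6 (0.0573), EE S2 replicate 3 (0.13), 5 (0.0512) or 6 (0.0706), SE P2 replicate 3 (0.0818), 4 (0.082) or 5 (0.0966) or EE P2 replicate 5 (0.101) or 6 (0.0609). Ube2r2 (adjusted p = 0.0314) lost it with the block (0.134) and without SE S2 replicate 3 (0.057), 4 (0.0937) or 5 (0.0841), EE S2 replicate 3 (0.0957) or 5 (0.0671), SE P2 replicate 3 (0.081), 4 (0.0578) or 5 (0.0966) or EE P2 replicate 5 (0.101). Values without a library for Fkbp5 and Nova2 stand with that comparison.

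Dixon's test marked a library far, relative to the range of its group, from the other 3 in 9 of 96 gene groups and 6 of 30 groups of library measures. It flags about 1 in 20 groups by chance. For Fkbp5 these were SE S2 replicate 5 (24.8 FPKM) and SS P2 replicate 6 (6.24 FPKM). For Pdia6 it was SS S2 replicate 3 (52.1 FPKM), and for Hspa5 SS S2 replicate 4 (93.7 FPKM) and EE P2 replicate 6 (234 FPKM). For Egr1 it was EE P2 replicate 5 (31.2 FPKM), for Camk2a SE S2 replicate 6 (480.3 FPKM), and for Mbp EE S2 replicate 5 (255 FPKM) and SS P2 replicate 3 (2138 FPKM). Named loci at 1 FPKM or more numbered 12986 in SS S2 replicate 3, against 13049 to 13060 in the rest of its group. They numbered 12289 in SS P2 replicate 3, against 12443 to 12461. Both gaps are small beside the counts and were marked because the rest of each group lay close together.

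Loci without a gene name, which no comparison used, held a larger share of the FPKM sum than in any SS library of the same fraction in EE P2 replicate 6 (17.8%) and in SE S2 replicates 3 (1.66%), 4 (2.70%) and 5 (2.00%). The share in SS S2 replicate 6 was 1.58%, against 1.26% to 1.29% in the rest of its group.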

How the results depend on the processing

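Removal of the GC and length trend, zeros as missing, the SE vs SS test in P2 without EE P2 replicate 6 and the list tests without that library, with another locus rule or after quantile normalisation were chosen after seeing the data. The read depth is unknown, so what it limits cannot be stated. Of 169 gene results 98 passed in limma, of which 74 did so under every alternative and 24 lost the threshold under at least 1, 21 of them when a library was left out. No gene result changed direction while past the threshold, but list medians and splits into higher and lower loci that turned are given with their comparisons. Of 507 list tests camera called 117, and 24 of these held with an estimated correlation, 90 with the GC and length trend removed and 111 with a replicate block. The 24 were the astrocyte, microglia, dendritic, glutamate receptor and extracellular matrix lists in the mean and all 3 treatments of P2 vs S2, the potassium channels in the mean and SS, and the glucocorticoid list for SE vs SS in both fractions. The 4 counts of P2 vs S2 stayed within 1.5 times under all alternatives.

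The cause of the following changes was not tested, except that fits on 8 libraries have fewer samples and the filters change the loci tested. With a mean of at least 5, the counts were 8 for SE vs SS in P2, and 2 and 5 for the fraction differences of SE vs SS and EE vs SE. Without a filter they were 0 for EE vs SS in P2, 1023 and 601 for EE vs SS and EE vs SE in S2, and 65 for the fraction difference of EE vs SS. Quantile normalisation gave 860 for the latter. With pseudocounts of 0.1 and 1, EE vs SS in P2 had 2 and 0. On 8 libraries alone the counts were 0 (EE vs SS in P2), 4 (EE vs SE in P2), 1006 (EE vs SS in S2) and 142 (EE vs SE in S2). With the GC and length trend removed, SE vs SS, EE vs SS and EE vs SE gave 36, 3 and 20 in P2 and 127, 1048 and 623 in S2.

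The pool was read from the replicate numbers, and 1 of 12 pairs of libraries so matched correlated over 0.1. With it as a block, the fraction differences of EE vs SS and EE vs SE gave 7 and 1, and the block changed no other count over 1.5 times. With the trend also removed, the fraction differences of SE vs SS, EE vs SS and EE vs SE gave 1, 11 and 3. Libraries of different treatments share only a number. Each library was set against the 4 libraries of each other treatment in its fraction, and in 16 of 48 such sets it correlated best with its own number. Each set is a choice of 1 among 4, so some such matches arise without any pairing. With that number as a block, EE vs SS in P2 gave 0 and SE vs SS in S2 37, and the calls of Acss3 for SE vs SS (adjusted p = 0.14) and EE vs SS (0.0921) in P2 and of Fkbp5 for EE vs SS in S2 (0.0621) were lost.

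With each library left out in turn, SE vs SS ranged from 4 to 18 in P2 and from 26 to 64 in S2, EE vs SS from 0 to 3 and from 491 to 2077, and EE vs SE from 4 to 8 and from 152 to 2010. The fraction differences ranged from 0 to 1 (SE vs SS), 7 to 3346 (EE vs SS) and 1 to 19 (EE vs SE).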

Other observations

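The list counts after quantile normalisation in this part were chosen after the results had been seen. Of 11 oligodendrocyte precursor markers 5 were higher in P2 than in S2 and 3 lower (7 and 1 after quantile normalisation), with a list median 0.69 above the median of all loci (camera adjusted p = 0.00262, and adjusted p = 0.167 with an estimated correlation). Ptprz1, a receptor phosphatase of precursors and astrocytes, lay 3.32 ± 0.08 above it and Pdgfra, the growth factor receptor of precursors, 1.86 ± 0.04, each in 12 of 12 pools. Of 18 GABA-A receptor and inhibitory scaffold genes 9 were higher and 4 lower (12 and 2 after quantile normalisation), with a median of 0.73 (adjusted p = 0.0038, and adjusted p = 0.32 with an estimated correlation). Of 11 genes of ethanol and acetaldehyde metabolism 7 were higher and 3 lower (8 and 3), with a median of 0.65 (adjusted p = 0.022, and adjusted p = 0.374 with an estimated correlation). Of 17 innate immune genes 8 were higher and 5 lower (12 and 3), with a median of 0.58 (adjusted p = 0.00859, and adjusted p = 0.32 with an estimated correlation). The list counts were the same adjusted over the list alone.

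Acss3 averaged 10.8 ± 2.11 FPKM in SS S2, 9.54 ± 3.12 in SE S2 and 5.28 ± 1.75 in EE S2 (SD, n = 4 each), beside 4.42 ± 0.899 in SE P2. Of 19 glycolysis genes 5 were higher in P2 and 13 lower (6 and 11 after quantile normalisation; camera adjusted p = 0.678), with Pgk1 at −0.79 ± 0.05 relative to the median of all loci. In EE S2 the mitochondrial leucyl-tRNA synthetase gene Lars2 was 1.25 ± 0.32 above SS S2 (limma adjusted p = 0.03) in 4 of 4 libraries, a call lost without a filter (0.0678) and without SS S2 replicate 5 (0.0734) or 6 (0.0768) or EE S2 replicate 3 (0.0581) or 5 (0.0511).

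Both mitochondrial loci (2) of the table were listed at 0 in all 12 P2 libraries and in 2 S2 libraries, and Lmbrd1 was listed at 0 in all 12 P2 libraries, so no fold is given for these. Of the loci with the highest and lowest fold changes, 11 of 12 for EE vs SS and 12 of 12 for EE vs SE in S2, 10 of 10 for the fraction difference of EE vs SS and 8 of 16 for P2 vs S2 lay at further loci of a symbol. Among all 12891 loci tested, 991 were further loci. Among called loci these were 185 of 1662 for EE vs SS and 94 of 1077 for EE vs SE in S2. They were 71 of 344 for the fraction difference of EE vs SS and 721 of 10828 for P2 vs S2.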
